A study of Homo sapiens with 8 samples.

How the data were processed

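RNA was measured in HCT116 cells with wild-type p53 (p53+/+), an established human colon cancer line, 24 hours after addition of 1 µM MANIO, a compound given here only by its code name, or of its solvent DMSO. The labels assign 4 samples to each group and describe them as biological replicates. Per the labels' protocols, total RNA was converted into libraries with Illumina's TruSeq RNA kit, version 2, and sequenced on an Illumina HiSeq instrument. That kit does not mark the strand, so reads from overlapping genes on opposite strands cannot be told apart.

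The authors deposited a table of raw read counts for 58302 Ensembl genes in the 8 libraries, as its whole-number values and column names show. Every line of the table names a gene, so no share of the counts was set aside, and every column of values belonged to one of the 8 samples. The submitters' processing notes name FastQC 1.3, STAR 2.5.3a, HTSeq and DESeq2 and the genome build GRCh38, without saying what each was used for. The annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. Counts of genes with near-identical copies, such as ribosomal protein, histone, keratin, heat shock and metallothionein genes, are therefore uncertain. Total counts ranged from 27945196 to 32509020 per library, while the labels state about 25M raw reads per sample; the reason for this difference is not given in the sources used here.

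Gene positions, types and spans were taken from GENCODE release 29 on GRCh38, which holds 58039 of the 58302 identifiers and 15673 of the genes tested. The span is the distance from a gene's first to its last annotated base, the exonic length is the length of its merged exons, and the GC content is that of its annotated transcripts. The share of a gene's exonic bases that lie in exons of another gene on either strand was computed as well and is given where it matters. Gene symbols are those of the deposited table.

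Counts were analysed in R 4.3.3. Genes with enough counts by edgeR's filterByExpr were kept, which left 15712, and libraries were scaled by the trimmed mean of M-values (TMM). Differences were tested with the quasi-likelihood F test of edgeR 4.0.16 with robust dispersion estimates and a model of group alone, and p-values were adjusted by the Benjamini-Hochberg method. An adjusted p under 0.05 was called, with no limit on fold. Log2 fold changes are MANIO over DMSO, standard errors (SE) come from the F statistic, and levels are TMM-scaled CPM (counts per 1e6 counts) with the SD over 4 libraries.

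A total of 33 gene lists had been fixed from general knowledge before the data were examined. They covered activated targets and regulators of p53, both parts of the cell cycle, apoptosis, several stress responses, lipid, energy and drug metabolism, ribosomes, signalling, differentiation and markers of other cell types. The 32 lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 32 lists. The test was repeated with an estimated correlation and with fry, which asks whether the genes of a list move on balance one way without comparing them with other genes. A p that camera or edgeR gives is named as such below.

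The rule for the genes named was also fixed beforehand. It takes 8 fixed genes, the 12 largest rises and the 12 largest falls among called genes with non-overlapping groups, an average log2 CPM of at least 1 and a symbol. It adds 6 further p53 targets with the smallest p, and from each other list 4 members with the smallest p where the list passed camera and 2 where it did not. A few genes outside the rule are named because a small count called for it or because they show the other direction within a list, and these were chosen after their values were seen. Some of the genes chosen by the rule are not reported here.

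Total counts, detected genes and the shares of counts in the 10 most abundant genes, in mitochondrially encoded genes and in cytosolic ribosomal protein genes were compared between groups by exact two-sided permutation tests over 70 assignments. The smallest p such a test can give is 0.0286. Libraries of a group differed from each other by 3.60 to 24.4 times the sampling noise (chi-square per degree of freedom), so none was a copy of another.

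The procedure was checked on simulated counts for the same comparison, drawn from the real means, dispersions and library sizes, with 50 genes changed at each of 4 fold sizes among 15318 tested. It recovered 20% of the genes changed 1.2-fold, 72% at 1.5-fold, 86% at 2-fold and 98% at 4-fold, and 13 of 151 calls (8.61%) were of unchanged genes. A simulated list shifted 1.2-fold was found by camera, and 0 of 50 unchanged lists were called. These shares are for simulated data with few changed genes and need not hold for the real comparison, in which many more were called. The simulated genes also varied independently of each other, and the simulated lists were random. How often camera makes false calls on lists whose genes move together was therefore not checked. In the real lists the estimated correlation ran from -0.054 to 0.886.

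Alternatives set beforehand were other scalings, other filters on low counts, DESeq2 1.42.0, limma-voom, the replicate number as a block, a surrogate variable from sva 3.50.0, protein-coding genes alone, a test against a 1.2-fold change and leaving out each library in turn. Added after seeing the data were a test of genes spanning under 50 kb alone, the removal of mitochondrially encoded genes, and the removal from each other list of members it shares with the p53 target list. Random lists and figures were made in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.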

Results

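The transcriptomes of 8 cultures of HCT116 p53+/+ cells were compared, 4 treated with 1 µM MANIO and 4 with DMSO for 24 hours. Total counts averaged 29.2 ± 1.78 M in the DMSO libraries and 31.0 ± 1.34 M in the MANIO libraries (SD, n = 4 each; exact permutation p = 0.171). The DMSO libraries held counts for 22792 ± 119 genes and the MANIO libraries for 23694.5 ± 167 (exact permutation p = 0.0286, the smallest possible with 4 against 4, and 0.143 after Benjamini-Hochberg adjustment over 5 library measures). Mitochondrially encoded genes took 5.64 ± 1.23% of the counts in DMSO and 7.08 ± 0.400% in MANIO, and the exact permutation p was 0.114. DMSO replicate 1 stood apart with a mitochondrial share of 7.48%, against 4.82% to 5.21% in the other DMSO libraries. Without that library the difference grew from 1.43 to 2.05 percentage points (adjusted exact permutation p = 0.0476). The 10 most abundant genes took 6.71 ± 0.974% of the counts in DMSO and 7.34 ± 0.294% in MANIO (exact permutation p = 0.257), a difference of 0.633 points that became 1.12 points without DMSO replicate 1 (adjusted exact permutation p = 0.0476). Cytosolic ribosomal protein genes took 7.54 ± 0.227% and 7.09 ± 0.289% (exact permutation p = 0.0857). The first principal component of log2 CPM carried 70.1% of the variance and separated the groups.

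The comparison was made to learn whether the compound engages the p53 response at the level of transcripts. Most established p53 target genes rose in the MANIO libraries. CDKN1A, which encodes the cell cycle inhibitor p21, went from 260 ± 24.0 CPM in DMSO to 1402 ± 97.1 CPM in MANIO (SD, n = 4 each), a 5.38-fold rise. MDM2, the ubiquitin ligase that restrains p53, rose 3.60-fold, from 199 ± 5.99 to 715 ± 52.7 CPM. The death receptor gene FAS rose 3.57-fold, from 25.5 ± 1.15 to 91.1 ± 6.37 CPM, and GDF15, a secreted stress cytokine, rose 3.90-fold, from 131 ± 20.2 to 509 ± 75.5 CPM. Of 100 tested members of the p53 target list, 92 rose, 45 of them at least 2-fold, 3 fell and 5 did not pass the test.

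All 4 MANIO libraries lay above all 4 DMSO libraries for each of the genes of this paragraph. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 3.4e-12 for CDKN1A (log2 fold change 2.43, SE 0.0750), 6.4e-12 for MDM2 (1.85, SE 0.0606), 1.2e-11 for FAS (1.83, SE 0.0638) and 4.6e-07 for GDF15 (1.96, SE 0.132). Genes for the pro-apoptotic proteins PUMA and BAX rose less: BBC3 had a log2 fold change of 0.93 (SE 0.0774) and BAX one of 0.91 (SE 0.0635), and TNFRSF10B, a receptor for the death ligand TRAIL, had one of 0.90 (SE 0.0470). Their adjusted p from edgeR's quasi-likelihood test was 1.4e-07, 2.3e-08 and 1.1e-09. On GRCh38, CDKN1A (ENSG00000124762) lies on chromosome 6 at 36676460 to 36687339, MDM2 (ENSG00000135679) on chromosome 12 at 68808176 to 68850686, and FAS (ENSG00000026103) on chromosome 10 at 88990582 to 89015785. The values count reads over each whole gene and do not separate exons or transcript forms.

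**Figure D1:**
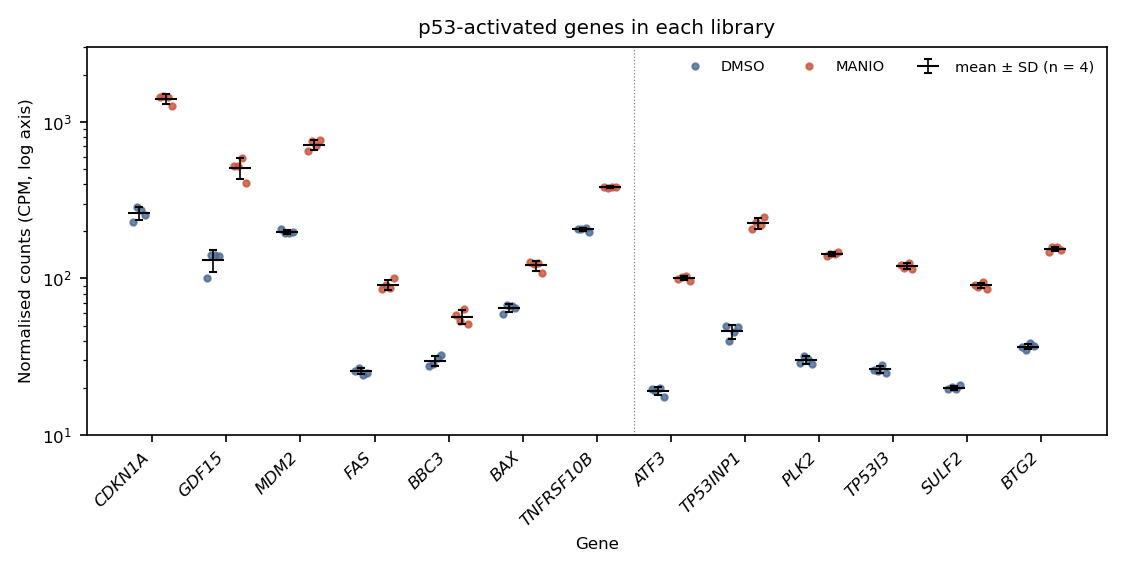
Normalised counts (CPM, log axis) of 13 p53-activated genes in each of the 4 DMSO and 4 MANIO libraries; points are libraries, and black marks are the mean with SD bars. CDKN1A moved from 260 to 1402 CPM and MDM2 from 199 to 715 CPM, and for every gene shown the MANIO points lie above the DMSO points.

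Beside these genes, the p53 targets with the smallest p were ATF3, PLK2, BTG2, TP53I3, SULF2 and TP53INP1. ATF3, a stress-induced transcription factor, went from 19.1 ± 1.04 to 100.04 ± 2.99 CPM (log2 fold change 2.39), and the kinase gene PLK2 from 30.1 ± 1.73 to 143 ± 3.52 CPM (2.25). TP53INP1 rose by 2.29 on the log2 scale, TP53I3 by 2.20, the sulfatase gene SULF2 by 2.17 and the antiproliferative gene BTG2 by 2.07. The 3 members that fell, all named after their values were seen, were KITLG, the gene of stem cell factor (-0.88), SUGCT (-0.72) and the translesion polymerase gene POLK (-0.33). LIF (-0.08), TNFAIP8 (-0.09), ARHGEF3 (-0.12), AIFM2 (0.12) and XPNPEP1 (0.01) did not pass. The median log2 fold change of the list was 0.91. Against all other tested genes its camera adjusted p was 2.5e-90, and 1.1e-05 with an estimated correlation. Adjusted over the list alone, the counts were the same, 92 and 3, as they were for 22 of the 33 lists. They are given below where they differed.

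Across the transcriptome, 8574 of 15712 tested genes (54.6%) were called by edgeR's quasi-likelihood test, 4366 higher and 4208 lower in MANIO. Most changes were small, with a median of 1.34-fold among called genes. At least 2-fold changes were found for 1083 genes, 711 higher and 372 lower, and at least 4-fold changes for 197, 138 higher and 59 lower. The groups did not overlap for 7593 genes (48.3%), where chance gives 2.86%. When changes were tested against a 1.2-fold limit with edgeR's glmTreat, 4132 genes were called, 2302 higher and 1830 lower, and without DMSO replicate 1 the count without such a limit was 8331. Camera found a shift for 16 of 32 lists, 7 upward and 9 downward, of which 5 also passed with an estimated correlation: the p53 targets, pro-apoptotic genes, ER chaperones, cholesterol synthesis and intestinal differentiation.

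The 12 largest rises were led by SYT8, a synaptotagmin gene that went from 0.282 ± 0.110 to 5.75 ± 0.746 CPM (log2 fold change 4.35). CEACAM1, an epithelial adhesion molecule, went from 1.398 ± 0.245 to 20.5 ± 1.18 CPM (3.88). PINCR, a long non-coding RNA on chromosome X, rose by 3.60 on the log2 scale, SORCS2 by 3.40, the gel-forming mucin gene MUC19 by 2.997 and the adhesion gene NECTIN4 by 2.92. The others were the lipid transporter gene ABCA12 (2.81), PLA2G4D (2.81), the glutamate receptor gene GRIN2C (2.80), KIAA1324 (2.78), HMCN2 (2.71) and the reductase gene AKR1B10 (2.67). The 12 largest falls were SSBP2 (-2.67), LRP1B (-2.31), AKAP6 (-2.30), TLN2 (-2.26), KCNQ1 (-2.20), XYLT1 (-2.18), DNM3 (-2.11), CNTN1 (-2.10), NBEA (-2.08), BANK1 (-2.06), FHIT (-2.04) and MAML3 (-2.04). Each of these 12 genes spans at least 339 kb, and LRP1B, a lipoprotein receptor family member, spans 1900.3 kb. SSBP2 went from 3.48 ± 0.374 to 0.545 ± 0.132 CPM, and the integrin adaptor gene TLN2 from 8.73 ± 0.365 to 1.82 ± 0.0555 CPM. All 24 genes had an adjusted p of 1.9e-06 or less in edgeR's quasi-likelihood test.

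**Figure D2:**
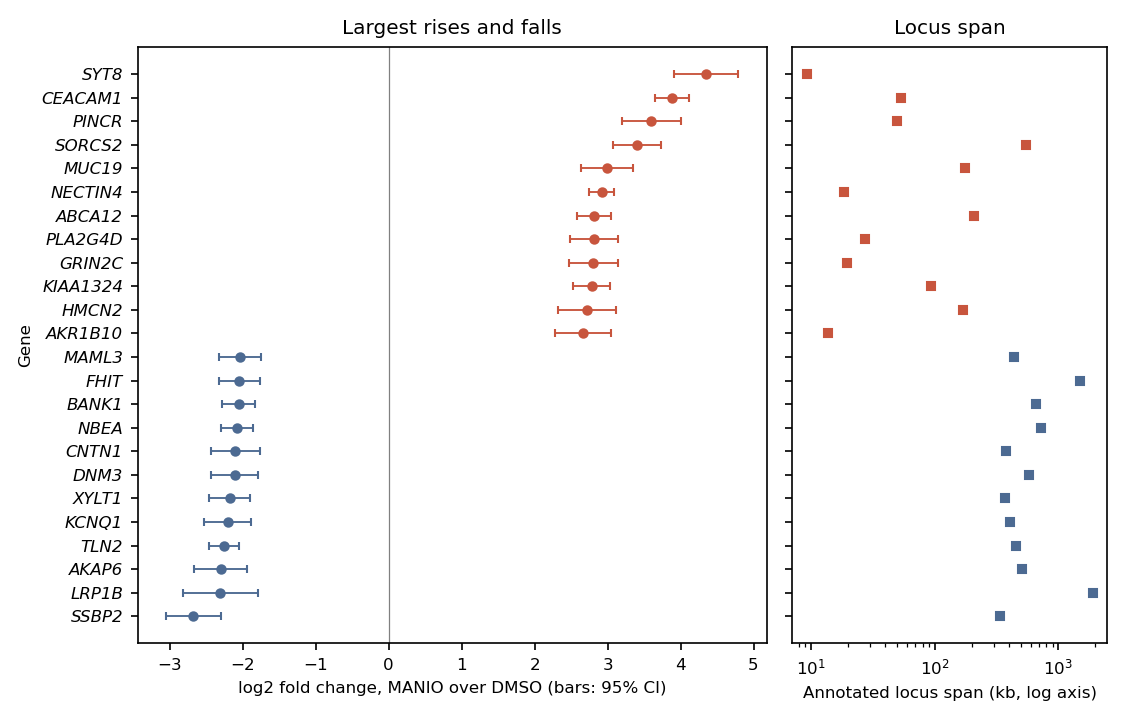
Left, log2 fold change (MANIO over DMSO, 4 against 4 libraries) of the 12 genes with the largest rise and the 12 with the largest fall, with 95% confidence intervals; right, the annotated span of each gene in kb on a log axis. The rises run from 2.67 to 4.35 and the falls from -2.67 to -2.04, and the genes that fell span 339 to 1900.3 kb.

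Genes of cell division fell together, by small amounts. Of 68 tested G2/M and mitosis genes, 57 fell, 1 rose and 10 did not pass, with a median log2 fold change of -0.39. DLGAP5, a spindle protein gene, went from 140 ± 6.02 to 80.1 ± 6.80 CPM (-0.80), the nuclear lamin gene LMNB1 from 219 ± 8.80 to 130 ± 6.17 CPM (-0.75), the kinetochore gene SPC25 from 35.7 ± 1.04 to 23.2 ± 0.672 CPM (-0.62) and the checkpoint kinase gene BUB1 from 168 ± 6.51 to 110 ± 6.61 CPM (-0.60). The member that rose, CDK1, encodes the mitotic kinase itself (0.22; named after its value was seen). Of 64 G1/S and DNA replication genes, 44 fell (45 adjusted over the list alone), 3 rose and 17 did not pass. RPA3, a subunit of the single-strand binding complex, fell by 0.77 on the log2 scale, the helicase gene MCM7 by 0.69, the primase gene PRIM1 by 0.67 and the polymerase gene POLA1, which spans 303 kb, by 0.65. The cyclin genes CCNE1 (0.48) and CCNE2 (0.47) and GINS4 (0.31) rose, and were named after their values were seen. By camera, the adjusted p was 3.0e-13 for the first list and 8.9e-08 for the second. With an estimated correlation camera's adjusted p was 0.253 and 0.376, so neither call was kept.

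Apoptosis genes moved in both directions. Of 27 pro-apoptotic genes, 15 rose and 4 fell, and TNFRSF10A, a second TRAIL receptor gene, rose by 0.73 on the log2 scale beside FAS, TNFRSF10B and BAX. Tested as a group with camera, these genes had an adjusted p of 1.7e-05, and 0.0171 with an estimated correlation. The list shares 8 genes with the p53 targets, all of which rose, and among the 19 others 7 rose and 4 fell (camera adjusted p = 0.428). Of 11 anti-apoptotic genes, 6 rose and 2 fell. The TRAIL decoy receptor genes TNFRSF10C (1.92) and TNFRSF10D (0.58) and the caspase 8 inhibitor gene CFLAR (1.08) rose, while BIRC5, the gene of survivin, fell (-0.46). In TNFRSF10C 39.3% of the exonic bases overlap another gene, which makes its count uncertain. Camera's adjusted p for this list was 0.00386, then 0.240 with an estimated correlation and 0.254 without the 2 genes shared with the p53 targets.

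Among 19 p53 regulators other than the targets, 6 rose (7 adjusted over the list alone) and 6 fell, and camera's adjusted p was 0.468. KAT5, an acetyltransferase gene, fell by 0.67 with 38.6% of its exonic bases overlapping another gene, and WWOX, which spans 1113.3 kb, fell by 0.98 on the log2 scale. Of 55 DNA repair genes, 16 rose and 17 fell (camera adjusted p = 0.5002). The damage recognition genes DDB2 (1.34) and XPC (1.19; 30.4% of its exonic bases overlap another gene) rose, and both are also in the p53 list. The median of the repair list was -0.01 while its mean was 0.06 and camera gave an upward direction. Without the 5 genes shared with the p53 targets the direction was downward (camera adjusted p = 0.382).

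Genes of lipid synthesis fell. Of 27 cholesterol synthesis genes, 22 fell, 1 rose and 4 did not pass, with a median log2 fold change of -0.47. INSIG1, a sterol-regulated ER protein gene, went from 118 ± 6.28 to 43.6 ± 3.13 CPM (-1.43), ACAT2 from 68.2 ± 5.03 to 39.6 ± 1.45 CPM (-0.78), the squalene epoxidase gene SQLE from 146 ± 5.06 to 90.4 ± 4.91 CPM (-0.69) and FDFT1 from 253 ± 6.88 to 173 ± 6.56 CPM (-0.55). In ACAT2 52.3% of the exonic bases overlap another gene. By the camera test, the adjusted p was 1.1e-09, and 0.00559 with an estimated correlation. Of 19 fatty acid synthesis genes, 12 fell and 2 rose. SCD, the stearoyl-CoA desaturase gene, fell by 1.23 on the log2 scale, ACSL3 by 0.86, and ELOVL6 and GPAM by 0.69 each. By camera, the adjusted p was 2.7e-04, but 0.0655 with an estimated correlation and 0.0673 among genes spanning under 50 kb.

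Chaperone genes of the endoplasmic reticulum (ER) fell as well. Of 27 ER chaperone and ER-associated degradation genes, 20 fell (21 adjusted over the list alone) and 2 rose. HSP90B1, an abundant ER chaperone gene, went from 1829 ± 126 to 1233 ± 63.7 CPM (-0.57), MANF fell by 0.60 on the log2 scale and the disulfide isomerase genes PDIA4 and PDIA6 by 0.53 and 0.48. In PDIA6 25.2% of the exonic bases overlap another gene. Tested as a group with camera, these genes had an adjusted p of 1.8e-04, and 0.0328 with an estimated correlation. Of 46 genes of the ATF4 integrated stress response, 23 fell and 12 rose. ATF3 and SESN2 (1.10), both p53 targets too, rose, and camera's adjusted p was 0.489. Among the 44 members outside the p53 list, 10 rose and 23 fell (camera adjusted p = 0.0740). The median of that list was -0.19 and its mean 0.01, and camera gave a downward direction. Of 23 cytosolic heat shock genes, 10 fell and 5 rose, among them the co-chaperone gene STIP1 (-0.45) and the constitutive chaperone gene HSPA8 (-0.44), with a camera adjusted p of 0.132.

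Of 75 nuclear genes of oxidative phosphorylation, 44 fell (45 adjusted over the list alone) and 1, NDUFA13, rose (0.64; named after its value was seen). ATP5MC2 fell by 0.91 on the log2 scale, ATP5ME by 0.55, NDUFB6 by 0.54 and NDUFB4 by 0.41, and in ATP5ME 61.6% of the exonic bases overlap another gene. By the camera test, the adjusted p was 1.1e-05, and 0.306 with an estimated correlation. Of 13 mitochondrially encoded mRNAs, 4 rose, 0 fell and 9 did not pass, and adjusted over the list alone edgeR's quasi-likelihood test called 0, although 6 had an unadjusted p under 0.05 in it. MT-CYB had a log2 fold change of 0.47 (edgeR adjusted p = 0.0336) and MT-ND2 one of 0.28 (edgeR adjusted p = 0.0235). Neither call was stable: MT-CYB lost it with DESeq2 (adjusted p = 0.0804), without a filter on low counts (edgeR adjusted p = 0.172) and in 6 of 8 edgeR fits with 1 library left out, and MT-ND2 lost it in 4 of those 8. Camera's adjusted p for this list was 0.216, but 4.8e-06 without DMSO replicate 1, the library with the highest mitochondrial share in its group.

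Of 40 hypoxia and glycolysis genes, 22 fell and 3 rose. The glycolytic genes ENO1 (-0.60) and LDHA (-0.61) fell, while the glucose transporter gene SLC2A1 (0.53) and the demethylase gene KDM4B (0.86) rose. By camera, the adjusted p was 0.0290, then 0.518 with an estimated correlation and 0.0598 without DMSO replicate 4. Of 78 cytosolic ribosomal protein genes, 22 fell (11 adjusted over the list alone) and 0 rose by edgeR's quasi-likelihood test, among them RPL35 (-0.34), RPL5, RPL8 and RPL41 (-0.27 each). Tested as a group with camera, these genes had an adjusted p of 0.0251, and 0.666 with an estimated correlation. Of 39 ribosome biogenesis and MYC genes, 14 fell and 12 rose (13 adjusted over the list alone). POLR1A (0.54) and MYC (0.42) rose, and camera's adjusted p was 0.831 with a downward direction, while the median was 0.04 and the mean 0.01.

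Redox and drug metabolism genes were mixed. Of 33 NRF2 genes, 15 fell (16 adjusted over the list alone) and 6 rose. The quinone reductase gene NQO1 went from 727 ± 48.1 to 385 ± 7.97 CPM (-0.92), while AKR1B10 was among the largest rises. By the camera test, the adjusted p was 0.0502, and 0.0426 with upper-quartile scaling. Of 12 genes on the aryl hydrocarbon receptor list, 3 rose and 2 fell (camera adjusted p = 0.585). Its members of smallest p were NQO1, which is also on the NRF2 list, and TRIB3 (-0.62). The median of this list was 0.06, its mean was -0.0012 and camera gave a downward direction. Of 13 xenobiotic metabolism genes, 5 rose and 2 fell (3 adjusted over the list alone), with a camera adjusted p of 0.142. ALDH1A3 (0.98; 28.6% of its exonic bases overlap another gene) and the carboxylesterase gene CES2 (0.88) rose. Of 7 metallothionein and zinc genes, the zinc exporter gene SLC30A1 (0.77) rose and 2 fell, MT1F (-1.21) and MT1X (-0.57; named after its value was seen), with a camera adjusted p of 0.585. Of 40 autophagy and lysosome genes, 17 rose (18 adjusted over the list alone) and 10 fell, with a camera adjusted p of 0.216. DRAM1, also a p53 target, rose by 1.13 and ATG10, which spans 305 kb, fell by 0.89 on the log2 scale.

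Of 38 interferon-stimulated genes, 18 rose and 1 fell. TRIM22, an antiviral gene that is also in the p53 list, went from 0.632 ± 0.0909 to 3.28 ± 0.309 CPM (2.36), and ISG20 (1.03), the peptide transporter gene TAP1 (0.82) and PARP14 (0.67) rose. The member that fell was IFIT1 (-0.91; named after its value was seen). By camera, the adjusted p was 0.0117, and 0.493 with an estimated correlation. Of 32 immediate early and MAPK feedback genes, 16 rose and 9 fell. JUN rose by 1.17, CCND1, the cyclin D1 gene, by 0.75 and the phosphatase gene DUSP5 by 0.64, beside ATF3. Tested as a group with camera, these genes had an adjusted p of 0.00627, then 0.266 with an estimated correlation, 0.103 without ATF3, the gene shared with the p53 targets, and 0.0845 among genes spanning under 50 kb. Of 24 NF-kB and cytokine genes, 11 rose, among them RELB (0.76) and NFKB2 (0.52), and 2 fell (camera adjusted p = 0.119).

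Of 21 WNT targets, 8 rose, among them DKK1 (0.79) and CCND1, and 6 fell (camera adjusted p = 0.390). The median of that list was -0.0021, its mean was 0.05 and camera gave an upward direction. Of 23 genes of epithelial-mesenchymal transition and invasion, 9 rose and 6 fell (camera adjusted p = 0.119). COL17A1, a hemidesmosome collagen gene, went from 2.502 ± 0.210 to 11.5 ± 1.21 CPM (2.19). The mesenchymal filament gene VIM fell (-1.71; named after its value was seen). Of 50 members of the list of replication-dependent histone genes only 15 were tested, of which 6 rose and 2 fell (camera adjusted p = 0.282). HIST1H2BD rose by 1.31, and H1F0, which encodes a linker histone made outside S phase, fell by 0.73 on the log2 scale.

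Intestinal differentiation genes were mostly too low to test, and most of those that could be tested rose. Of 37 list members 9 were tested, 7 rose and 2, KRT20 (-0.04) and HNF4A (0.09), did not pass. Beside CEACAM1, the goblet cell mucin gene MUC2 went from 0.156 ± 0.0740 to 1.76 ± 0.560 CPM (3.46), the carbonic anhydrase gene CA2 from 60.1 ± 4.21 to 107 ± 7.39 CPM (0.84) and the keratin gene KRT19 from 721 ± 44.7 to 981 ± 59.9 CPM (0.44). By the camera test, the adjusted p was 4.9e-06, and 0.0171 with an estimated correlation.

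Few markers of cell types other than the line itself could be tested. Of 12 fibroblast markers 4 were tested and 4 rose: COL1A1 from 22.9 ± 2.21 to 42.2 ± 3.44 CPM, ACTA2 from 5.05 ± 0.707 to 18.8 ± 1.22 CPM, COL5A1 from 0.246 ± 0.0887 to 0.860 ± 0.0275 CPM and PDGFRB from 0.402 ± 0.0431 to 0.836 ± 0.268 CPM. In ACTA2 30.1% of the exonic bases overlap other genes, and its span overlaps the start of FAS, so its count is uncertain. By camera, the adjusted p was 1.8e-04, and 0.0611 with an estimated correlation. Of 4 tested leukocyte markers 2 rose (3 adjusted over the list alone), ITGAM (1.98) and HLA-DRA (0.60), with a camera adjusted p of 0.170. The neuronal markers MAP2 (-1.15; it spans 310 kb), SYP (-1.19) and ENO2 (-0.36; 99.2 CPM in DMSO and 77.2 CPM in MANIO) fell, and TUBB3 (-0.07) did not pass. Camera's adjusted p for these 4 was 0.0260, then 0.240 with an estimated correlation and 0.0848 among genes spanning under 50 kb. The 1 endothelial marker tested, VWF, fell by 1.35 on the log2 scale, from 0.778 ± 0.204 to 0.302 ± 0.117 CPM.

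**Figure D3:**
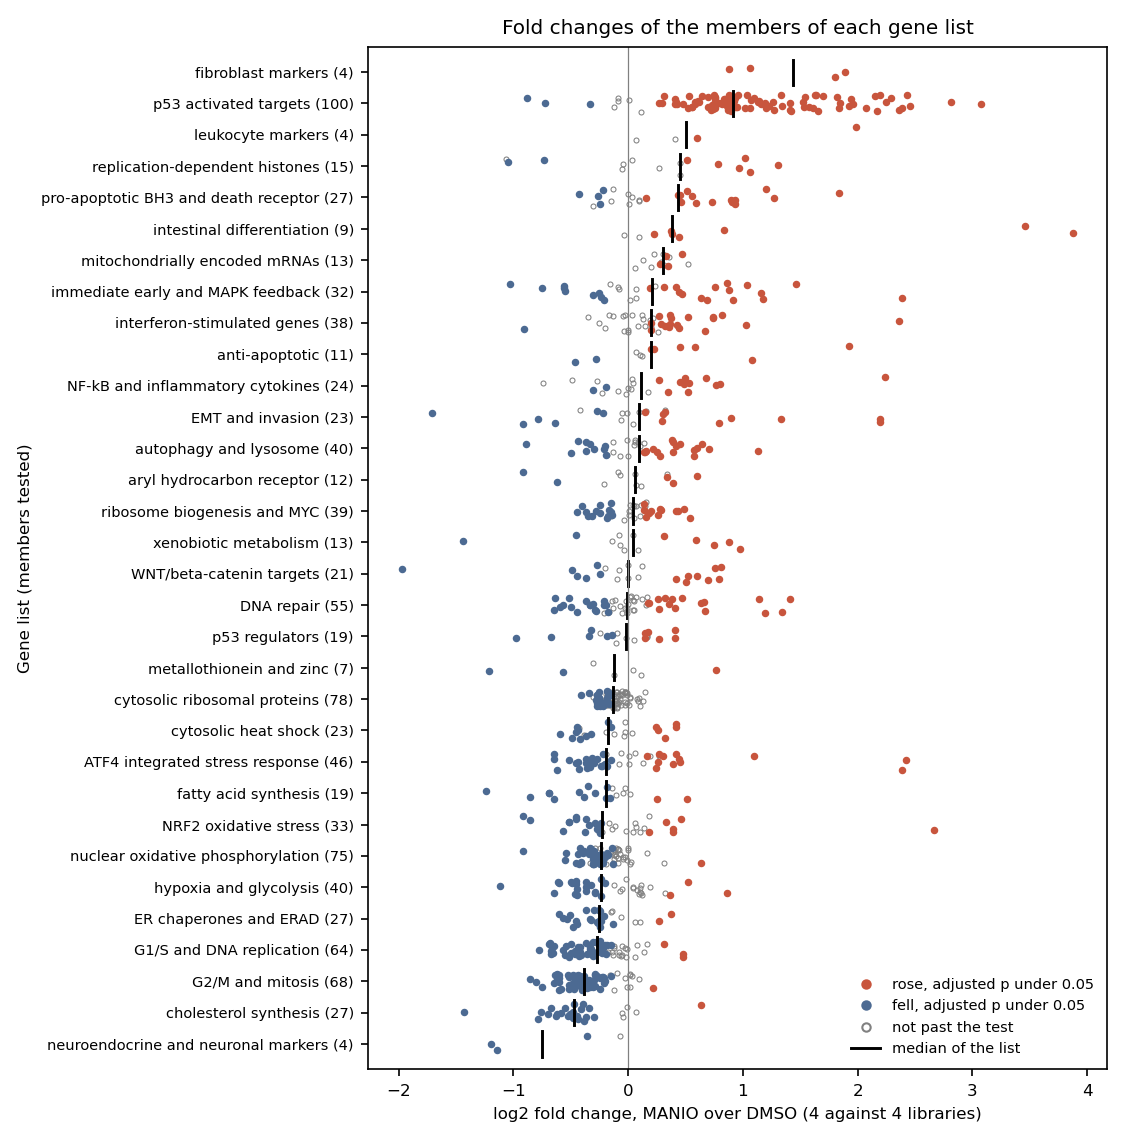
Log2 fold change (MANIO over DMSO, 4 against 4 libraries) of every tested member of the 32 lists with at least 3 tested members, ordered by the list median (black bar); filled points rose or fell with an adjusted p under 0.05 by edgeR's quasi-likelihood test, and open points did not pass. The p53 targets lie to the right with a median of 0.91, and cholesterol synthesis (-0.47) and G2/M genes (-0.39) lie to the left.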

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

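The split test below was set before its result was seen. A library was picked out where its gap to the nearest library of its own group of 4 took up so much of the group's range as chance gives in about 1 of 20 groups. Of 254 groups tested, 17 met this, where chance gives about 12.7. DMSO replicate 1 was the library in 8 cases, MANIO replicate 4 in 5, MANIO replicate 3 in 2, and MANIO replicates 1 and 2 in 1 each.

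DMSO replicate 1 was highest in its group for the share of the 10 most abundant genes (8.16%, the others 6.09% to 6.30%) and for the mitochondrial share (7.48%, the others 4.82% to 5.21%). It was also highest for MT-ND2 (2851 CPM, the others at most 2076 CPM), MT-CYB (3920 CPM, the others at most 2377 CPM) and NBEA (12.9 CPM, the others at most 10.6 CPM). It was lowest for GDF15 (100.4 CPM, the others at least 139 CPM), NFKB2 (98.1 CPM, the others at least 111 CPM) and CCND1 (469 CPM, the others at least 522 CPM).

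MANIO replicate 4 was lowest in its group for CDKN1A (1257 CPM, the others at least 1445 CPM), BAX (108 CPM, the others at least 124 CPM), KDM4B (64.6 CPM, the others at least 77.8 CPM), XYLT1 (1.14 CPM, the others at least 1.52 CPM) and PDGFRB (0.437 CPM, the others at least 0.919 CPM). MANIO replicate 3 was highest for MUC2 (2.59 CPM, the others at most 1.52 CPM) and lowest for NDUFB6 (36.0 CPM, the others at least 39.8 CPM). MANIO replicate 2 was lowest for ISG20 (5.73 CPM, the others at least 6.87 CPM). MANIO replicate 1 had the highest ribosomal protein share of its group (7.52%, the others 6.92% to 6.98%).

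Of the 35 ways to split the 8 libraries into 4 and 4, 1, the real one, gave as many as 8574 genes by edgeR's quasi-likelihood test. The highest of the others gave 1 gene. Each of the others mixes MANIO and DMSO libraries on both sides, which widens the spread within its groups, so few calls were likely beforehand. The test thus cannot exclude chance beyond a share of 1 in 35. Nor can it tell the treatment from another difference that follows the groups. The number of lists past camera was 16 in the real split and 1 to 12 in the 18 splits with equal numbers of MANIO and DMSO libraries on each side. In the 16 splits that exchange 1 library per group and so keep part of the real contrast it was 8 to 18. The camera p of the p53 target list was 7.9e-92 in the real split, 1.6e-24 to 5.1e-14 in those 16 and 0.470 to 0.989 in the 18 even ones.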

How the results depend on the processing

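Alternatives restricted to genes under 50 kb, without mitochondrial genes or without p53 targets in other lists were chosen after seeing the data. The count of 8574 genes stayed between 7563 and 9406 under other scalings, filters and tools, a surrogate variable and protein-coding genes alone, and between 7818 and 8622 when single libraries were left out. DESeq2 called 8271 genes, 7868 of them among the 8574, and limma-voom 8564, with 8499 shared. A test against a 1.2-fold change called 4132 (2302 higher, 1830 lower), since it asks for more than a change from 0. Among genes under 50 kb, where 10529 were tested, 5416 were called (2825 higher, 2591 lower). Rising p53 targets numbered 89 to 93, and 68 under 50 kb, where fewer were tested; the list passed in each of the 18 alternatives in which it was tested. Of the 31 other lists, 15 passed, against 4 with an estimated correlation and 26 with fry, which compares a list with no other genes, and 12 to 17 otherwise. The ribosome biogenesis list, never past the threshold, turned upward with fry (adjusted p = 0.975) and without DMSO replicate 2 (0.790) or MANIO replicate 4 (0.9985), within a range of 0.498 to 0.9985 over single libraries left out; the cause was not tested. DNA repair turned downward without shared p53 targets (0.382), of which 4 had risen. Genes named by the rule kept their calls in the alternatives in which they were followed, except MT-CYB and MT-ND2, which lost them in 14 cases. Single genes were not followed in the test against a 1.2-fold change. Genes named outside the rule were not followed in any alternative. The camera adjusted p of the NRF2 list (0.0502) lay between 0.00548 (no filter on low counts) and 0.518 (estimated correlation), and fry gave 0.00306. Over single libraries left out, the group difference was 848 to 979 for detected genes, 0.426 to 1.12 points for the 10 most abundant genes and 1.16 to 2.05 points for the mitochondrial share; these 3 passed without DMSO replicate 1 alone (exact permutation, adjusted p = 0.0476). The model of group alone had been set beforehand, since the labels do not say that replicate numbers mark a shared day or culture. Same-numbered samples had correlations of deviations of 0.038, 0.16, 0.12 and 0.096, not all above 0.1, and not every sample correlated best with its own number. On the second principal component (8.1% of the variance), replicates 1 and 2 of both groups were negative and replicates 3 and 4 positive. What this reflects was not tested. With the replicate number as a block edgeR called 8845 genes, 8459 of them shared. Counting all lines of the table in place of those naming a gene changes nothing, since every line names one. What depth limits was not tested by varying it; in a simulation at this depth with few changed genes, 20% of 1.2-fold changes were found.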

Other observations

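The 4 lists of the first 2 paragraphs, the comparison of long loci with matched genes, the test of a graded fall, the trend with span with 1 property held nearly fixed and the form of the fibroblast test used here were chosen after results were seen. The other tests had been set before. Of 23 tested genes of hemidesmosomes and epithelial adhesion, 16 rose and 1, PKP2, fell (-0.37), with a median log2 fold change of 0.55. LAMA3, a laminin chain gene, went from 6.70 to 33.2 CPM (2.31), the serpin gene SERPINB5 from 47.7 to 195 CPM (2.03) and SFN, the 14-3-3 sigma gene, from 207 to 561 CPM (1.44). The gap junction gene GJB5 (1.47) and the keratin genes KRT17 (2.18) and KRT15 (1.43) rose, while DSG2 (0.06) did not pass. Of 12 long non-coding RNAs known to respond to p53, 9 rose, PINCR and the p53 list member PVT1 (0.41) among them, and 1 fell. PURPL went from 0.204 to 2.49 CPM (3.61), the miR-34a host gene MIR34AHG from 3.78 to 12.97 CPM (1.77) and MIR22HG from 4.02 to 9.49 CPM (1.24). LINC-PINT fell (-0.60), with 29.6% of its exonic bases overlapping another gene. Because these lists were assembled after genes in them had stood out, no list test is given for them.

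Of 18 antigen presentation genes, 10 rose and 3 fell. The peptidase gene ERAP2 rose by 1.19, TAP1 by 0.82 and HLA-B by 0.49, while the chaperone genes PDIA3 (-0.45), CALR (-0.33) and CANX (-0.30) fell. Of 20 NOTCH pathway genes, 8 rose and 2 fell. NOTCH3 (1.06) and NOTCH1 (0.80) and the ligand genes JAG2 (0.64) and DLL1 (0.63) rose. The coactivator genes MAML3 (-2.04) and MAML2 (-1.76), which span 437 and 367 kb, fell, and of the NOTCH targets HEY1 (0.55; from 0.577 to 0.851 CPM) rose, while HES1 (0.18), NRARP (0.24) and HES4 (0.12) did not pass.

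Protein-coding genes with a span of at least 200 kb mostly fell: 571 of 909 fell and 109 rose, with a median log2 fold change of -0.35, and 70.1% of the 304 genes that fell at least 2-fold spanned at least 100 kb, against 19.2% of all. Genes under 100 kb were matched to these 909 on exonic length, GC content, mean expression or all of them together. Their medians were 0.090, -0.034, 0.042 and 0.077, which argues against each as the whole cause of the fall in long loci. The 95% ranges lay between -0.058 and 0.114 and cover only the draw of matched genes. They leave out the spread of the 909 genes and of the libraries, and how close the matches were was not checked. Over all spans the trend (rho = -0.162 across 12920 genes, which are not independent replicates) was uneven within bins: rho ran from -0.344 to -0.059 over 5 bins of exonic length, from -0.223 to 0.090 over those of GC content and from -0.308 to 0.063 over those of expression, and by the test set before, each stays open as a part of the trend. The log2 fold change followed GC content more strongly than span (rho = 0.207 across 12914 genes) and exonic length only weakly (rho = 0.039). Averaged within 20 narrow bins, rho with span was -0.238 with exonic length held nearly fixed (95% range -0.255 to -0.220) and -0.137 with expression held so (-0.154 to -0.121), which argues against either as the whole cause. With GC content held so it was -0.079 (-0.096 to -0.060), so a weaker trend with span remained. That range stayed negative but fell short of the limit set for this test. GC content as the whole cause therefore stays undecided. A fall in output that grows with span, as an effect on transcript elongation might give, is a candidate explanation for the group difference. Among p53 targets, those in longer loci rose less (rho = -0.202 across 99 genes, permutation p = 0.0441). That permutation treats genes as independent, and its rho is near the -0.162 of all genes, so it adds little beyond the general trend. The medians did not fall at every step (0.0043 under 10 kb, 0.042 from 10 to 25 kb, 0.026, -0.011, -0.060 and -0.35 from 200 kb). A graded fall therefore cannot be told apart from other sources of the trend, and elongation was not measured. The median of long genes ran from -0.97 in the lowest of 5 expression bins (genes under 100 kb there 0.17) to -0.14 in the highest (-0.067). It was 0.044 for the 24 long genes of highest GC content (0.12).

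Of the nuclear genes of oxidative phosphorylation 44 of 75 fell and of the ribosomal protein genes 22 of 78, and neither list kept its camera call with an estimated correlation (adjusted p = 0.306 and 0.666); both have short transcripts, the loss of which could give such falls. The median of the first list was -0.24, at percentile 0.05 of 10000 random lists matched on exonic length and mean expression. The median of those random lists was -0.11. Their members were drawn singly, so their spread leaves out that genes of this list move together (estimated correlation 0.173). With this limit the percentile cannot decide on short exonic length as the whole cause of that fall. Exonic length merges the exons of all annotated transcripts and can exceed the length of the transcript in use. The test therefore cannot decide on a loss of short transcripts themselves. The median of the ribosomal protein list, -0.13, lay at percentile 99.89 of its matched lists, whose median was -0.24. A fall shared by genes of like exonic length and expression may therefore account for it. Other causes of either fall, the treatment among them, stay open.

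The 4 fibroblast markers tested, of 12 listed, rose in the MANIO libraries, and cells of that type in the cultures are one possible explanation. As a list they lost their camera call with an estimated correlation (adjusted p = 0.0611). COL1A2, COL3A1, DCN and LUM, abundant in fibroblasts, together gained 0.027 CPM, against 14.8 CPM for ACTA2, COL5A1 and PDGFRB, which argues against fibroblasts as the source. ACTA2, whose span overlaps that of FAS, made up 13.7 CPM of that gain, and the other markers with 1.05 CPM still exceeded the abundant genes. In a first form of the test, with COL1A1 among the abundant genes, the gain was 19.3 CPM, all but 0.027 CPM of it from COL1A1. Expression of COL1A1 by the HCT116 cells themselves stays open, as do reads of FAS counted for ACTA2, and neither was tested.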
